A study of Homo sapiens with 4 samples.

How the data were processed

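Polyadenylated RNA of TPC-1 and B-CPAP, 2 established human lines of papillary thyroid carcinoma, was sequenced in 4 libraries, 1 of each line at 37 °C and 1 at 40 °C. The labels state the length of the exposure in 3 ways, as 15 min in the growth protocol, 20 min in the series design and 24 h in the treatment label, and the length is therefore left open here. Per the labels' protocols, RNA was extracted with RNeasy Plus and libraries were made with TruSeq RNA Library Prep Kit v2, a kit that does not mark strand, so reads of overlapping genes on opposite strands cannot be told apart. Per the submitters' processing notes, the authors used FastQC, MultiQC, Trimmomatic 0.38, featureCounts 2.0.0 and the GRCh38 genome; the aligner and the annotation release are not given in the sources used here.

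The deposited table holds TPM, which is expression scaled by gene length and by the library's total, for 58884 Ensembl gene IDs in 4 columns, and each column sums to 1000000. Of these IDs, 58611 (99.5%) were found in GENCODE 29 on GRCh38, which gave the coordinates, exon lengths and GC contents used here, and 58472 had a symbol in the name table. TPM keeps no depth. Multiplying TPM by GENCODE 29 exon length gave values in steps of whole reads, with 90.5 to 92.0% of values up to 20 reads whole within 0.02 of a read and 65.7 to 67.6% of values between 20 and 200 reads. The estimated depth was 22054713 reads for TPC-1 at 37 °C, 20704722 for TPC-1 at 40 °C, 24466576 for B-CPAP at 37 °C and 23232350 for B-CPAP at 40 °C. These estimated reads served for exact (Clopper-Pearson) 95% intervals of TPM ratios between 2 libraries. The intervals cover counting error only, compare 2 libraries and not 2 conditions, and leave out any spread between cultures. No test of counts was run.

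Values were analysed as log2(TPM + 1), and fold changes are on that scale, which understates changes of low genes; TPM ratios are named as ratios. Genes with a mean TPM of at least 1 over the 4 libraries were tested, 14912 in all, of which 11824 were protein-coding. Within a line each temperature had 1 library, so differences between temperatures have no replicate check and carry no p-value; genes 2-fold or more apart were counted. Over both lines, 40 °C was compared with 37 °C by limma 3.58.1 (R 4.3.3) with the line as a block, and B-CPAP with TPC-1 with temperature as a block. Each fit had 1 residual degree of freedom per gene, an intensity trend, two-sided tests and Benjamini-Hochberg adjustment at 0.05. The labels do not say that libraries came from separate cultures beyond their line and temperature. The spread left in each fit is how far the difference between temperatures differs between the 2 lines. These p-values set an effect against that spread and hold no spread between cultures of a group. The fits were tested on simulated data with 14912 genes, of which 200 were changed, with results averaged over 10 simulations. The comparison of temperatures recovered 42% of 2-fold and 76.3% of 4-fold changes with 8.2 false calls. The comparison of lines recovered 42.4% and 77.4% with 13.8 false calls. Over the 10 simulations the recovery of 2-fold changes ran from 31 to 68% for temperatures and from 6 to 65% for lines. Far more than 200 genes were called between the real lines (9349), so the simulated rates need not hold for that comparison. The simulated noise was independent between genes and libraries. These rates therefore do not cover an effect shared by a library, such as the trend with GC content described below.

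In all, 31 gene lists with 687 entries were fixed before the data were examined, of which 28 had at least 3 tested genes. In each line a list's median log2 difference was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A median below percentile 2.5 or above 97.5 was taken to stand apart, which about 5% of lists do by chance. Over the libraries the lists were tested with camera (limma) at a preset inter-gene correlation of 0.01 and again with an estimated correlation. The choice of named genes was also fixed in advance. It took the 10 largest differences each way in each line at a mean TPM of at least 5, up to 15 genes each way that differed 2-fold in both lines (1.5-fold where under 5 qualified). It also took up to 5 members of each list by the mean of both lines' differences, every member of the cytosolic heat shock list, and the 12 genes highest in each line past the adjusted p of 0.05. Rows without a symbol, clone and locus names, small RNA families, pseudogenes and sex-linked marker genes were passed over. Some genes that the rule takes are not reported here.

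The alternatives were other pseudocounts (0.1 and 5), no filter, a mean TPM of at least 5, centring on the median, quantile normalization, TPM rescaled without mitochondrially encoded genes, other limma settings, the fit without the block, and fits leaving out 1 library. Added after seeing the data were protein-coding genes only, a demand that the counting interval exclude 1, and an adjustment for GC content. In the adjustment each library's deviation from the gene means was fitted by loess (span 0.5) on GC content and removed, with or without a second fit on length. A gene's GC content was taken over all its annotated transcripts, so sequence shared by several of them counted more than once. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.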

Results

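RNA of the papillary thyroid cancer lines TPC-1 and B-CPAP was compared between 37 °C and 40 °C to ask how thermal stress alters the transcriptome of thyroid cancer cells. Each of the 4 groups held 1 library, at an estimated depth of 20704722 to 24466576 reads. Protein-coding genes took 91.6 to 93.2% of TPM. Mitochondrially encoded genes took 16.8% of TPM in TPC-1 at 37 °C and 19.9% at 40 °C, and 22.0% and 23.9% in B-CPAP.

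The heat shock genes of the cytosolic list, most of which encode chaperones and co-chaperones, lay within the range of random lists at 40 °C in both lines. In TPC-1, 13 of the 26 tested members were higher at 40 °C and the median log2 difference was -0.00013, at percentile 83.8 of random lists, with a mean of 0.07. In B-CPAP, 15 members were higher and the median was 0.08, at percentile 88.6. The stress-inducible HSPA1B (ENSG00000204388, chromosome 6, 31827735 to 31830255) stood at 36.1 TPM at 37 °C and 41.5 TPM at 40 °C in TPC-1 (ratio 1.15, interval 1.02 to 1.29), and at 130.8 and 136.6 TPM in B-CPAP, where the counting interval of the ratio, 0.987 to 1.11, included 1. Its near-identical neighbour HSPA1A was listed at 0.13 to 0.63 TPM, so the level of either gene is uncertain, since reads that match both cannot be assigned. HSPA6, which is strictly stress-induced, reached at most 0.74 TPM in any library. DNAJB1, an HSP40 co-chaperone, was lower at 40 °C in both lines, at 144.8 against 162.8 TPM in TPC-1 and 257.0 against 290.9 TPM in B-CPAP.

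Within this group, which also holds the mitochondrial chaperonins HSPD1 and HSPE1 and the transcription factors HSF1 and HSF2, members went both ways. The inducible HSP90 gene HSP90AA1 (ENSG00000080824, chromosome 14, 102080738 to 102139699) stood 1.29-fold higher in the 40 °C library of TPC-1 (705.3 against 545.0 TPM; interval 1.27 to 1.32) and 1.62-fold higher in that of B-CPAP (935.5 against 577.8 TPM; interval 1.59 to 1.65). HSPE1, the mitochondrial co-chaperonin, was 1.40-fold and 1.37-fold higher, and its partner HSPD1 1.11-fold and 1.38-fold higher. In B-CPAP the TPM ratio was 2.04 for DNAJB4, 2.06 for CHORDC1, 1.88 for HSPA4L, 1.48 for HSPH1, 1.38 for DNAJA1, 1.37 for HSF2, 1.35 for CACYBP and 1.32 for HSPA4; in TPC-1 these ratios lay between 0.984 (HSPA4) and 1.32 (HSPA4L). The heat shock regulator HSF1 was lower at 40 °C, with ratios of 0.798 and 0.688, as were HSPB1 (0.881 and 0.754), DEDD2 (0.843 and 0.697), FKBP4 (0.844 and 0.856) and SERPINH1 (0.941 and 0.890). The ratios in TPC-1 and B-CPAP were 0.973 and 0.816 for BAG3, 0.951 and 0.825 for HSPB8, 0.926 and 0.986 for STIP1, 0.996 and 1.05 for AHSA1 and 1.01 and 0.871 for HSPA2. CRYAB stood at 0.15 and 0.88 TPM in TPC-1 and at 3.46 and 2.74 TPM in B-CPAP. HSPA8 had ratios of 0.952 and 1.11 and HSP90AB1 of 0.943 and 1.06. Over both lines, limma called 0 of the 26 members over all genes. Adjusted over the list alone it called 2, HSPE1 (log2 difference 0.46, adjusted p = 0.0445) and HSP90AA1 (0.53, adjusted p = 0.0445), both higher in 2 of 2 lines. When protein-coding genes alone were fitted, a choice made after seeing the data, limma called 7 members higher and 2 lower, and 1 higher and 0 lower once values were adjusted for GC content. At a mean TPM of at least 5 it called 5 of 23 members higher and 2 lower, and 0 once adjusted.

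**Figure D1:**
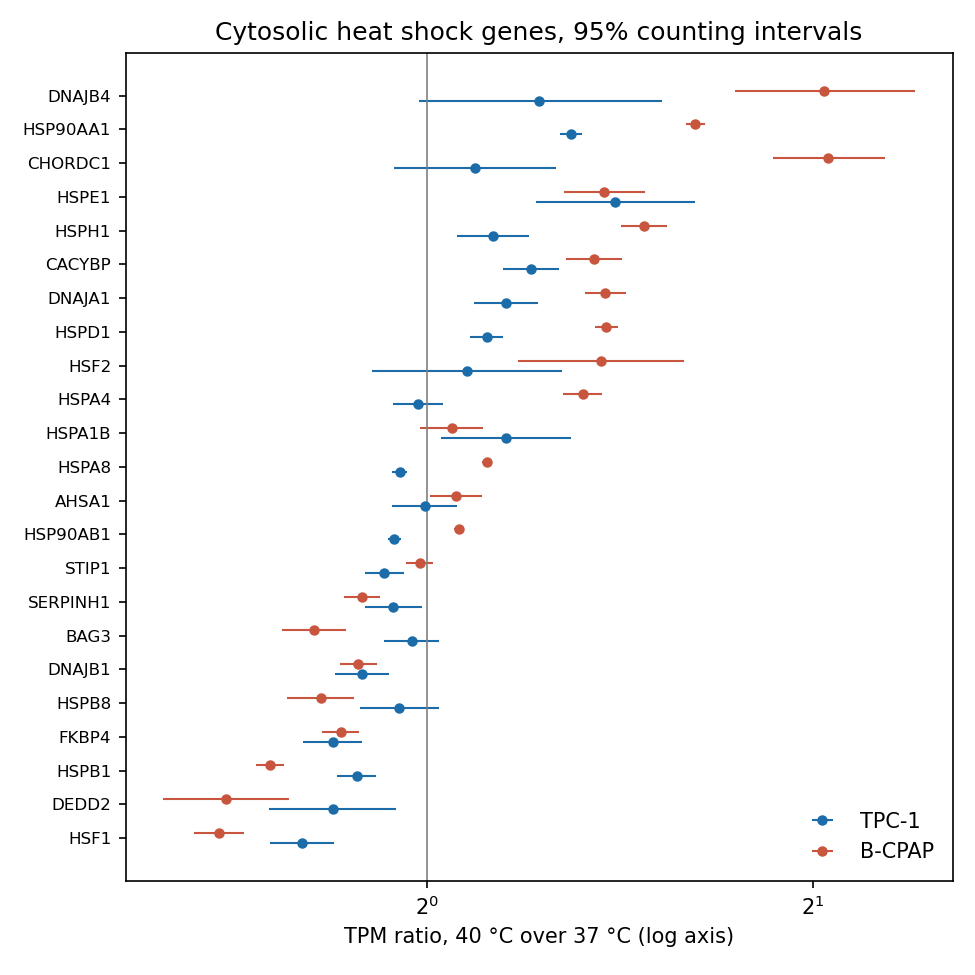
Ratio of TPM at 40 °C over 37 °C (log axis) for the cytosolic heat shock genes with a mean TPM of at least 5, each point from 2 libraries of a line and bars for 95% counting intervals. In B-CPAP the ratios run from 0.688 for HSF1 to 2.06 for CHORDC1, and in TPC-1 from 0.798 for HSF1 to 1.40 for HSPE1.

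In TPC-1, 336 genes stood 2-fold or more higher and 183 lower at 40 °C, and few of them were protein-coding genes (10 higher, 8 lower). The higher side held the mitochondrial tRNAs MT-TI at 21.6 and 70.2 TPM, MT-TS2 at 53.2 and 158.4 TPM and MT-TE at 28.8 and 72.8 TPM. As the libraries are of polyadenylated RNA and keep no strand, reads on mitochondrial tRNA genes may belong to neighbouring transcripts. The levels of these tRNAs, here and below, are therefore uncertain. MT-TK was listed at 0 and 2.47 TPM from 0 and 1 reads and MT-TA at 4.79 and 12.5 TPM from 2 and 5 reads, with counting intervals that included 1. The protein-coding genes among the 10 largest differences at a mean TPM of at least 5 were COX7B, a subunit of cytochrome c oxidase (15.1 and 31.8 TPM; ratio 2.11, interval 1.82 to 2.44), TXNDC9 (ratio 2.13), KRCC1 (ratio 2.06) and MAGEA3. MAGEA3 encodes a cancer-testis antigen (0.09 and 1.17 TPM) and is uncertain because of its near-identical relatives. The noncoding transcript PIWIL2-DT stood at 1.93 and 8.07 TPM. The 10 largest on the lower side were the vault RNA VTRNA1-2 (39.0 and 13.6 TPM), the transcription factor BATF3 (3.60 and 1.21 TPM; ratio 0.336), EEF1AKMT4 (ratio 0.426), TRAPPC14 (ratio 0.463), C6orf226 (ratio 0.551), EVA1B (ratio 0.593), the mitochondrial tRNA MT-TV (52.7 and 30.1 TPM) and the noncoding RNAs MUC12-AS1, PRR34-AS1 and PCAT6; the intervals of MT-TV and MUC12-AS1 included 1. Of the genes 2-fold apart, 174 on the higher and 103 on the lower side were shorter than 200 bases, and the counting interval excluded 1 for 98 higher and 40 lower genes.

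In B-CPAP, 414 genes stood 2-fold or more higher and 168 lower at 40 °C, and the protein-coding genes among them were almost all higher (134 higher, 3 lower). Of all genes 2-fold apart 71.1% were higher, and 53.6% were under quantile normalization. The mitotic kinesins CENPE (3.51 and 13.8 TPM; ratio 3.93, interval 3.41 to 4.54) and KIF20B (9.84 and 34.4 TPM; ratio 3.50) were among the 10 largest. So were the Golgi protein gene GOLGA4 (7.49 and 23.8 TPM; ratio 3.18), ASPM, which acts at the spindle pole (5.53 and 17.2 TPM; ratio 3.12), and ESF1 (12.5 and 37.2 TPM; ratio 2.99), with MT-TR, MT-TK, MT-TH, MT-TG and MID1IP1-AS1. In TPC-1 the ratio was 0.898 for CENPE, 0.978 for KIF20B, 0.901 for GOLGA4, 1.03 for ASPM and 1.05 for ESF1. The lower side held the hair keratin gene KRT81 (2.29 and 0.52 TPM), CTXN1 (ratio 0.493), MTFP1 (ratio 0.492), the chorionic gonadotropin subunit gene CGB5 (ratio 0.522, uncertain because of its near-identical copies), CAMK1 (ratio 0.477), the proton pump subunit gene ATP6V0C (66.8 and 37.9 TPM; ratio 0.567), VTRNA1-2 (1 and 0 reads, an interval that included 1), HM13-IT1, PPP1R15B-AS1 and PIK3CD-AS2. The 134 protein-coding genes on the higher side had a median exon length of 7958 bases and a median GC content of 38.4%, against 5116 bases and 49.2% for all tested protein-coding genes. Of them, 10 were still 2-fold higher once values were adjusted for GC content.

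The difference between temperatures followed the GC content of the transcripts in both lines. Across 11819 protein-coding genes, which are not independent replicates, Spearman's rho between the log2 difference and GC content was -0.60 in TPC-1 and -0.82 in B-CPAP. Genes with a GC content up to 42.0% had a median difference of 0.21 in TPC-1 and 0.52 in B-CPAP, and those from 58.6% had -0.15 and -0.29. A straight line in GC content took up 30.3% of the variance of these differences in TPC-1 and 63.3% in B-CPAP. Among the 2823 genes with a mean TPM of at least 50, rho was -0.72 and -0.86. Across the protein-coding genes rho was -0.06 and -0.13 after the adjustment for GC content, which therefore did not remove the trend in full. The difference between the lines was less tied to GC content, with rho 0.11 at 37 °C and -0.05 at 40 °C.

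**Figure D2:**
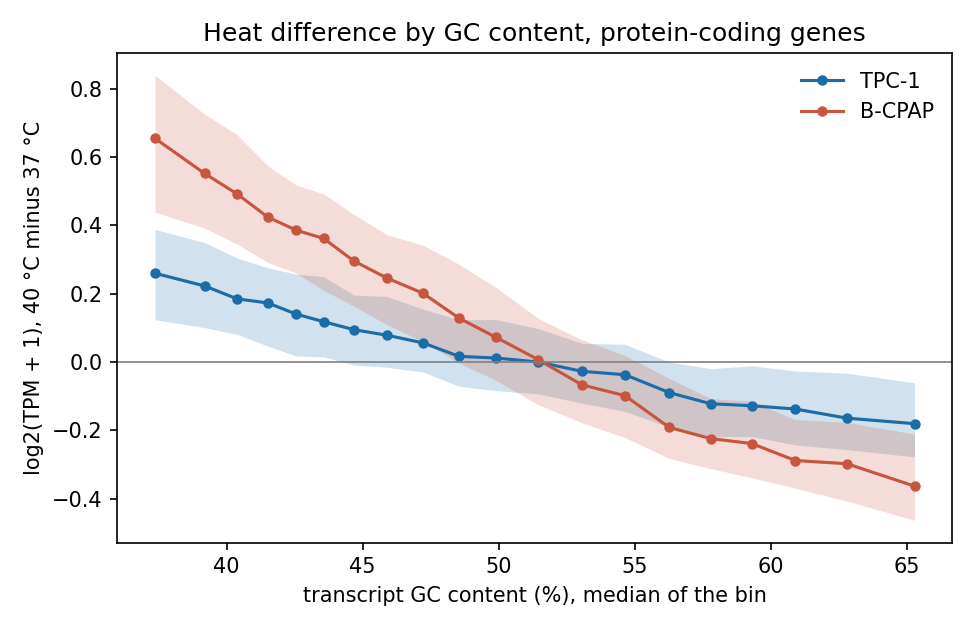
Difference in log2(TPM + 1) between 40 °C and 37 °C against transcript GC content (%) for 11819 protein-coding genes in 20 bins, points for bin medians and bands for quartiles over genes. Both lines slope down, with rho -0.60 in TPC-1 and -0.82 in B-CPAP.

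Among the fixed lists, 7 of 28 stood apart in TPC-1 and 5 in B-CPAP. Once adjusted for GC content 8 and 4 did, and 4 and 1 of these had stood apart before with the same sign. In TPC-1 the p53 targets (percentile 99.8), antioxidant genes (2.13) and fibroblast markers (0.19) stood apart only once adjusted. In B-CPAP the antioxidant genes (1.85), the matrix and adhesion genes (99.9) and the mitochondrially encoded genes did so. The median of the 9 fibroblast markers in TPC-1 was 0 before the adjustment and -0.23 after it. The adjustment also shifts genes without reads, so this low place is no measured fall. In TPC-1 the 13 mitochondrially encoded genes had a median log2 difference of 0.35 (percentile 100), with all 13 higher at 40 °C. They were led by MT-ND6 (2602 and 4147 TPM), MT-ND5 (3108 and 4696 TPM) and MT-ATP8 (3337 and 4906 TPM). In B-CPAP 11 were higher and the median was 0.10 (percentile 96.2), or -0.20 (percentile 0.335) once adjusted for GC content, against 0.21 in TPC-1. The 9 tested nuclear-retained and host-gene RNAs had medians of 0.51 (percentile 100) in TPC-1 and 0.37 (percentile 95.9) in B-CPAP, and 0.37 (percentile 100) and 0.05 (percentile 84.3) once adjusted for GC content. The RNA-binding genes with temperature-sensitive splicing had medians of 0.18 (percentile 99.9) and 0.28 (percentile 98.6), with CLK1, a splicing kinase, at ratios of 1.60 and 1.77 and TRA2A at 1.20 and 1.78; adjusted for GC content, the medians were 0.07 (percentile 99.8) and -0.05 (percentile 51.6). The chaperonin and prefoldin genes had medians of 0.05 (percentile 98.5) and 0.16 (percentile 98.3), with VBP1 at ratios of 1.37 and 1.41. Once adjusted for GC content their medians were -0.10 (percentile 39.5) and -0.08 (percentile 53.9). The genes of hypoxia and glycolysis, 1 joint list, were lower in TPC-1 (median -0.17, percentile 0.2), with 22 of 25 not higher. In B-CPAP the median was -0.08 (percentile 34.5) and 10 of 25 were higher. Once adjusted for GC content the medians were -0.17 (percentile 0.135) in TPC-1 and -0.06 (percentile 54.4) in B-CPAP. Of members lower in both lines, ALDOA had ratios of 0.720 and 0.695 in the 2 lines, PFKL 0.785 and 0.784, and GAPDH 0.781 and 0.805. Ribosomal protein genes (median 0.00497, percentile 99.9) and nuclear genes of oxidative phosphorylation (median 0.03, percentile 98.4) also stood apart in TPC-1; adjusted for GC content both medians were -0.05, at percentile 99.8 for the ribosomal genes and 89.2 for the others, and the ribosomal median was -0.02 when libraries were centred on the median.

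In B-CPAP the endoplasmic reticulum chaperone genes stood higher (median 0.30, percentile 99.8), with HSP90B1 at 225.6 and 391.9 TPM and SEL1L at a ratio of 1.67. So did the genes of homologous recombination repair (median 0.45, percentile 99.5), among them NBN at a ratio of 2.17 and RBBP8 at 1.76. The genes of the G2 and M phases also stood higher (median 0.22, percentile 99.6), with CENPF at a ratio of 2.77, HMMR at 1.93, KIF11 at 1.77 and CDK1 at 1.60. In TPC-1 the medians were -0.00462 for the chaperones (percentile 74.0), 0.06 for the repair genes (percentile 46.5) and -0.00290 for the G2 and M genes (percentile 84.0). After adjustment for GC content the B-CPAP medians were 0.07 for the chaperones (percentile 99.8), 0.08 for the repair genes (percentile 88.6) and 0.01 for the G2 and M genes (percentile 97.3).

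For 40 °C against 37 °C over both lines, limma called 0 of 14912 genes, and the smallest adjusted p was 0.0871. An unadjusted p under 0.05 was found for 2905 genes, against 745.6 from chance alone. On values adjusted for GC content it was found for 1633, and 0 genes were called. The count of called genes depended on which genes entered the fit. With a mean TPM of at least 5, limma called 867 of 10112 genes (508 higher, 359 lower), and with protein-coding genes only, a choice made after seeing the data, 1350 of 11824 (880 higher, 470 lower). The called genes parted by GC content, with medians of 40.3% for those higher and 61.3% for those lower among protein-coding genes. Once values were adjusted for GC content, 31 and 30 genes were called, of which 28 and 25 were among the earlier 867 and 1350.

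Camera at the preset correlation called 5 of 28 lists over both lines. The mitochondrially encoded genes (adjusted p = 0.000318), the nuclear-retained RNAs (adjusted p = 0.00502), the temperature-sensitive RNA-binding genes (adjusted p = 0.00582) and the repair genes (adjusted p = 0.0257) rose. The genes of hypoxia and glycolysis fell (adjusted p = 0.000318). With an estimated correlation 0 lists were called (adjusted p = 0.956 for each of the 5). On 1 residual degree of freedom this setting could hardly call any list, so it cannot decide on the 5. On values adjusted for GC content, at the preset correlation, the genes of hypoxia and glycolysis (adjusted p = 0.0178) and the nuclear-retained RNAs (adjusted p = 0.000975) were still called. The mitochondrially encoded (adjusted p = 0.845), RNA-binding (adjusted p = 0.318) and repair genes (adjusted p = 0.39) were not. The 2 lists still called stood apart after the adjustment in TPC-1 alone. Hypoxia and glycolysis lay at percentile 0.135 in TPC-1 and 54.4 in B-CPAP, and the nuclear-retained RNAs at 100 and 84.3. The antioxidant genes (adjusted p = 0.00847) and the genes of cholesterol synthesis (adjusted p = 0.0149), which were not called before the adjustment, were called lower after it. Adjusted over the list alone, limma called 6 of the 9 nuclear-retained RNAs, all higher at 40 °C, among them MALAT1 (125.5 and 203.1 TPM in TPC-1, 85.5 and 218.7 TPM in B-CPAP) and NEAT1 (9.26 and 16.0 TPM, 13.6 and 27.0 TPM). It also called 6 of 13 mitochondrially encoded genes, 8 of 25 genes of hypoxia and glycolysis, 25 of 53 ribosomal protein genes and 10 of 19 antioxidant genes. Further calls were 8 of 37 oxidative phosphorylation genes, 4 of 33 proteasome genes, 3 of 23 G2 and M genes and 1 of 21 apoptosis genes. Ribosomal protein genes went both ways, with RPS24, RPS27A and RPL7 higher and RPLP0, chosen after its values were seen, lower. Among the antioxidant genes TXN (422.0 and 591.3 TPM in TPC-1, 466.8 and 647.1 TPM in B-CPAP) was higher and OSGIN1 (30.9 and 24.0 TPM, 26.0 and 18.1 TPM) lower, and the apoptosis gene was PMAIP1, a BH3-only gene (6.36 and 12.8 TPM, 13.2 and 21.7 TPM).

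The 2 lines' log2 differences correlated across genes with Pearson's r 0.20 and Spearman's rho 0.45, and with r 0.53 among protein-coding genes, where r was 0.18 after adjustment for GC content. Genes are not independent replicates, and the lines share no control library. Both lines had 65 genes 2-fold higher, where independent lists would share 9.33, and 26 genes 2-fold lower, against 2.06. A further 81 genes were 2-fold apart in opposite directions, against 8.87, so the excess is not one of shared direction alone. Of the genes 2-fold apart the same way, 1 was protein-coding, the histone gene H2AC12. The named genes higher in both lines were MT-TK, MT-TE, MT-TI, H2AC12 and the antisense RNAs OCIAD1-AS1 and FARSA-AS1, and of these MT-TE alone had counting intervals that excluded 1 in both lines. At 1.5-fold, genes lower in both included VTRNA1-2, F12, ATP6V0C, FAM110A, CGB5, HNRNPD-DT, TRIM7-AS2, TONSL-AS1 and ARHGEF17-AS1. Of these, F12, ATP6V0C, FAM110A and ARHGEF17-AS1 had counting intervals that excluded 1 in both lines, and VTRNA1-2 rested on 1 and 0 reads in B-CPAP. ATP6V0C had ratios of 0.645 and 0.567 and FAM110A of 0.637 and 0.628. The differences between the lines' responses have no residual degrees of freedom and were not tested.

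B-CPAP and TPC-1 differed in most tested genes. Limma called 9349 of 14912 genes between B-CPAP and TPC-1, 4457 higher in B-CPAP and 4892 higher in TPC-1, of which 2342 and 2558 differed 2-fold or more. Fits on 3 libraries, without the temperature block, called 3014 genes without TPC-1 at 37 °C, 2911 without TPC-1 at 40 °C, 5101 without B-CPAP at 37 °C and 5719 without B-CPAP at 40 °C, where the lone library is assumed to vary like the others. B-CPAP expressed ANKRD1, a target gene of YAP signalling (543.4 and 627.4 TPM at 37 °C and 40 °C, against 0.08 and 0 TPM in TPC-1; log2 difference 9.13, SE 0.13, adjusted p = 1.93e-05). It also expressed the carboxypeptidase gene CPA4 (log2 difference 8.78), THY1 (8.01), the phosphatase gene ACP5 (7.99), LCP1, which encodes an actin-bundling protein (7.60), the prostaglandin synthase gene PTGES (7.31) and the activin subunit gene INHBA (7.22). PAGE2, PAGE5, MAGEB2, CRABP1 and TIMP3 were listed at 0 in both TPC-1 libraries and reached 338.6, 311.0, 160.9, 200.3 and 150.8 TPM in B-CPAP at 37 °C; the first 3 are cancer-testis antigens, and PAGE2 has a near-identical copy and is uncertain. TPC-1 expressed the NADPH oxidase gene NOX5 (1358 and 1217 TPM, against 0.05 and 0.06 TPM in B-CPAP; log2 difference -10.25, SE 0.11, adjusted p = 1.60e-05). It also expressed the deubiquitinase gene UCHL1 (-9.22), SCARA3 (-7.76), SLPI (-7.39), HAVCR1 (-7.21), SERPINA1 (-7.15), PXDN (-6.96), WNT7B (-6.87) and DHRS3 (-6.74). FAM20C (496.7 TPM in TPC-1 at 37 °C) and MYL9 (135.5 TPM) were listed at 0 in both B-CPAP libraries.

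**Figure D3:**
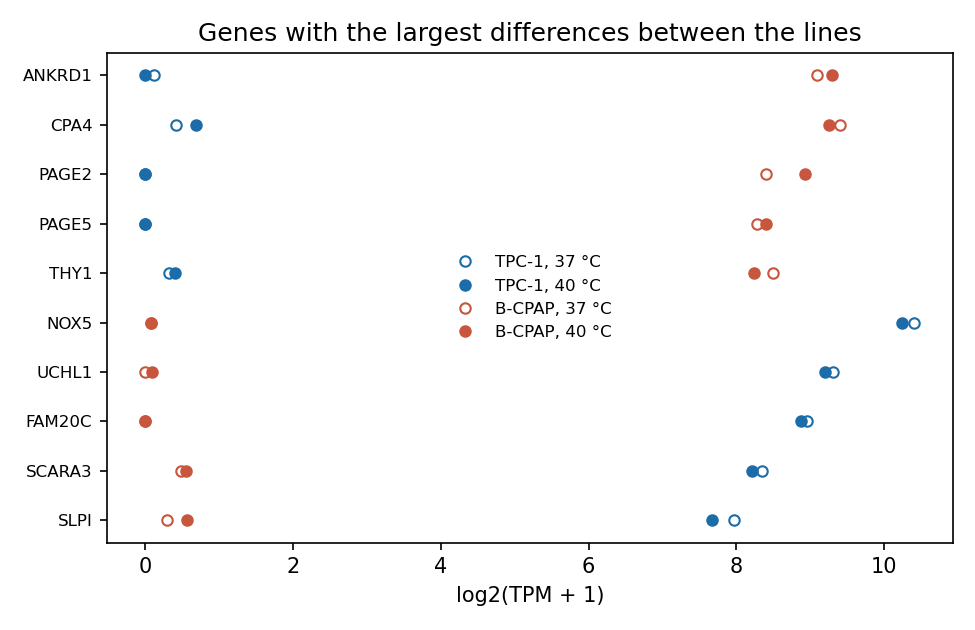
Expression as log2(TPM + 1) of the 5 genes with the largest difference in favour of each line, 1 point per library, open at 37 °C and filled at 40 °C. For every gene the 2 libraries of a line lie together and apart from those of the other line, as for NOX5 with 1358 and 1217 TPM in TPC-1.

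Camera called 8 of the fixed lists between lines at the preset correlation. With an estimated correlation 0 of these 8 were called. The adjusted p was 0.821 for the p53, ERK, heat shock, replication, ribosomal and fibroblast lists. It was 0.881 for hypoxia and glycolysis and 0.875 for the mitochondrial genes. On 1 residual degree of freedom this setting could hardly call any list, so it cannot decide on the 8. At the preset correlation, the p53 target genes were lower in B-CPAP, with 15 of 19 members lower, 3 higher and 1 not called (camera adjusted p = 0.00349). CDKN1A, the p21 cell cycle inhibitor, stood at 312.1 and 316.0 TPM in TPC-1 and 13.6 and 9.28 TPM in B-CPAP, and GDF15 at 44.0 and 51.8 against 0.39 and 0.48 TPM. Of the 15 ERK output genes 10 were lower in B-CPAP and 2 higher (adjusted p = 0.0129), among them PHLDA1 (log2 difference -2.57) and DUSP6 (-2.33). Of the cytosolic heat shock genes 17 of 26 were higher in B-CPAP and 3 lower (adjusted p = 0.00383), HSPA1B with a log2 difference of 1.76. Of the 25 genes of DNA replication 12 were higher and 2 lower (adjusted p = 0.0202), with CCNE1 at 3.66 and MCM7 at 2.14. Of 25 genes of hypoxia and glycolysis 17 were lower and 3 higher (adjusted p = 0.00515), and of 53 ribosomal protein genes 34 were lower and 7 higher (adjusted p = 0.0018). Of 13 mitochondrially encoded genes 11 were higher and 2 lower (adjusted p = 0.00835), and of 9 fibroblast markers 7 were higher and 0 lower (adjusted p = 0.00976), led by THY1 and TAGLN (106.1 and 80.8 against 4.90 and 3.14 TPM). Of the members named for this comparison, CDKN1A, GDF15, DUSP6, CCNE1 and MCM7 were chosen after their values were seen.

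Thyroid follicular markers were sparse in both lines, with 5 of 18 tested, of which limma called 3 lower and 1 higher in B-CPAP. PAX8 stood at 284.4 and 266.7 TPM in TPC-1 and 111.9 and 98.9 TPM in B-CPAP, and NKX2-1 was listed at 0 in TPC-1 and at 8.60 and 7.90 TPM in B-CPAP. SLC5A5, chosen like TG after its values were seen, was listed at 0 in every library, and TG reached at most 0.75 TPM. A single leukocyte marker (CSF1R) and a single endothelial marker (ROBO4, 25.6 and 20.4 TPM in TPC-1) passed the expression filter, and no erythroid marker did.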

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

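The rule used here, that a named gene had counting intervals on opposite sides of 1 in the 2 lines, was chosen after the data were seen. It picked 3 of 232 named genes. Of the 232, 32 had opposite signs, 2 were 1.5-fold apart in opposite directions and 0 were 2-fold apart in opposite directions. On values not adjusted for GC content 0 gene lists stood apart in opposite directions; once adjusted, the mitochondrially encoded genes did, with medians of 0.21 (percentile 100) in TPC-1 and -0.20 (percentile 0.335) in B-CPAP. The difference between the lines was not tested for any of them, since no residual degrees of freedom are left.

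CENPE, a mitotic kinesin, had a log2 difference between 40 °C and 37 °C of -0.14 in TPC-1 and 1.71 in B-CPAP, 1.86 apart. HSPA8, the constitutive cytosolic HSP70, had -0.07 and 0.16, which is 0.23 apart. HSP90AB1, the constitutive HSP90, had -0.09 and 0.08, which is 0.17 apart.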

How the results depend on the processing

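Protein-coding genes only, the counting interval and the GC adjustments were chosen after seeing the data. With 1 library per group, depth limits genes of few reads, and the counts of genes 2-fold apart moved with the pseudocount and the filter; except where fewer genes were tested or counted by construction, the cause was not tested. In TPC-1 the 336 genes higher and 183 lower were 639 and 348 with a pseudocount of 0.1, 58 and 31 with 5, and 803 and 488 with no filter. They were 41 and 22 at a mean TPM of at least 5, 10 and 8 among protein-coding genes and 98 and 40 where the counting interval excluded 1. In B-CPAP the 414 and 168 were 879 and 367, 53 and 29, 783 and 360, 143 and 32, 134 and 3, and 222 and 49 under the same settings, and those higher were 211 with GC adjustment and 218 with GC and length adjustment. In both lines the 65 higher and 26 lower were 133 and 47 with a pseudocount of 0.1, 4 and 3 with 5, and 11 and 8 at a mean TPM of at least 5. They were 1 and 0 among protein-coding genes and 221 and 67 at 1.5-fold; those higher were 40 with GC adjustment and 38 with GC and length adjustment.

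For temperature over both lines limma called 0 genes (2905 at an unadjusted p under 0.05), 2 with a pseudocount of 5, 867 at a mean TPM of at least 5, 1350 among protein-coding genes, and 31 and 30 when these last 2 choices were joined with GC adjustment. Without the block (the line for temperature, the temperature for line) limma called 0 genes for temperature and 7469 for line, against 0 and 9349 with it. For temperature this fit leaves the differences between the lines in the residual, so its 0 calls are no check. Leaving out 1 library gave 2911 to 5719 genes between lines; for temperature it leaves 1 pair and no test with the block. Camera called 0 lists with an estimated correlation for temperature, against 5, and 0 for line, against 8. On 1 residual degree of freedom that setting could hardly call any list, so it is no check on these calls.

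The correlation of the lines' differences across genes, Pearson's r 0.20, was 0.449 as Spearman's rho, 0.516 at a mean TPM of at least 5, and 0.381 with a pseudocount of 5. It was 0.115 with no filter, 0.535 among protein-coding genes, 0.0519 with GC adjustment and 0.0560 with GC and length adjustment. The heat shock median in TPC-1, -0.00013, was 0.0473 without mitochondrially encoded genes, 0.0653 as a mean, -0.0640 with GC adjustment and -0.0481 with GC and length adjustment. In B-CPAP 0.08 became -0.0154 with GC adjustment and -0.0115 when centred on the median. It was 0.00425 with GC and length adjustment and 0.148 as a mean. With GC adjustment the heat shock medians lay at percentile 63.7 of random lists in TPC-1 and 90.0 in B-CPAP, against 83.8 and 88.6 before.

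Among lists that stood apart, 5 medians changed sign, and the cause was not tested. In TPC-1 the ribosomal median was -0.0216 when centred, -0.0493 with GC adjustment and -0.0420 with GC and length adjustment. That of oxidative phosphorylation was -0.0460 and -0.0389 with these adjustments, and that of chaperonins -0.102 and -0.0869. In B-CPAP the chaperonin median was -0.0798 and -0.0547 and that of RNA-binding genes -0.0540 and -0.0714. These signs do not give the place among random lists, whose medians were often negative too after GC adjustment. With it the percentiles in TPC-1 were 99.8 (ribosomal), 89.2 (oxidative phosphorylation) and 39.5 (chaperonins). In B-CPAP they were 53.9 (chaperonins) and 51.6 (RNA-binding genes), so none of the 5 medians stood apart on the low side. Of the other values for single genes and lists under the alternatives, 4031 stayed within their spread and 852 moved beyond it; the sign differed in 114 and 127 of these, medians of lists that had not stood apart among them.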

Other observations

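Apart from the fixed histone list and its percentiles, the tests in this part were chosen after the results were seen, as were the genes named. Among protein-coding genes, limma called 25 genes between temperatures both before and after adjustment for GC content, 17 higher and 8 lower at 40 °C in both lines. The adjustment left a weak trend with GC content (Spearman's rho -0.06 in TPC-1 and -0.13 in B-CPAP). Of the 30 genes called after it, those higher had a median GC content of 47.2% and those lower 51.5%. The 25 can therefore not be taken as free of the trend. With GC adjustment and a mean TPM of at least 5 instead, limma called 4 of the 25 (DBI, NDUFB3, RPS24 and ATP6V0C); 16, HSP90AA1 among them, were not called and 5 were not tested, so most of these calls rest on the choice of genes fitted. Beside HSP90AA1, those higher included COX6C (41.9 and 72.9 TPM in TPC-1, 48.8 and 76.3 TPM in B-CPAP) and NDUFB3 (31.5 and 51.7 TPM, 80.0 and 140.9 TPM) of the respiratory chain. RPS24 and RPS27A of the ribosome, and the proton pump subunit gene ATP6V1G1 (57.9 and 81.9 TPM, 137.3 and 194.7 TPM), were also higher. The replication-dependent histone genes H4C1, H2BC10, H2AC12 and H2AC14 were also among them, at under 5 TPM in every library and with near-identical relatives, so their levels are uncertain. Their counting intervals included 1 in both lines, except that of H2AC14 in TPC-1. Of the 26 tested histone genes of the fixed list 6 were higher and 7 lower in both lines, and the medians were -0.03 (percentile 3.75) and 0.04 (percentile 18.6). Of the 25 genes, those lower included the metallothionein gene MT2A (1029 and 819.5 TPM, 1148 and 711.9 TPM), the tubulin genes TUBA1B (1284 and 1050 TPM, 1448 and 1103 TPM) and TUBA1C, which share much of their sequence, S100A11 (4299 and 3431 TPM, 2400 and 1980 TPM), CSRP1, PLP2, FPR1 and ATP6V0C.

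Of 21 mitochondrial tRNAs tested, 14 stood higher at 40 °C in TPC-1 (median log2 difference 0.32) and 16 in B-CPAP (median 0.63). Once adjusted for GC content 11 and 12 stood higher, with medians of 0.04 and 0.20. As stated above, reads on these genes may belong to neighbouring transcripts.

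AT-rich transcripts stood higher in the 40 °C library of each line. Transcript length does not account for this, since Spearman's rho with GC content was -0.59 in TPC-1 and -0.81 in B-CPAP with length held fixed. Within 3 complexes (ribosome, oxidative phosphorylation and proteasome, 123 genes), members moving together do not account for this either. The pooled slope within them was -0.31 in TPC-1 and -0.39 in B-CPAP per 10 points of GC (permutation p = 1e-04 in each, the smallest 10000 permutations can give). Genes are not independent replicates, and other pathways were not tested in this way. A GC-dependent difference between libraries may account for the trend, as the slope within the complexes was 2.02 and 1.10 times that over all protein-coding genes. An effect of temperature on AT-rich RNA itself predicts the same slope and stays open, untested, as each line has 1 library per temperature.

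FP236383.3, an annotated gene in a ribosomal DNA repeat (chromosome 21, 8437629 to 8438551, GRCh38), stood at 434.6 TPM at 37 °C and 6563 TPM at 40 °C in B-CPAP, and at 1428 and 2052 TPM in TPC-1. Reads moved among 4 near-identical copies on chromosome 21 do not account for this, since their sum was 9.69-fold higher in B-CPAP (counting interval 9.41 to 9.98). The repeat also occurs outside chromosome 21, and reads moved to or from those copies were not tested. Carry-over of ribosomal RNA into the library, which could bring reads of the same repeat, cannot be told apart from a change in the cells. The 5.8S genes summed to a ratio of 1.28 on 20 and 24 reads (interval 0.678 to 2.44). They are another part of the repeat and cannot test carry-over of the stretch that holds FP236383.3. The gene ends 1272 bases before a 5.8S gene on the opposite strand, and the library keeps no strand. A response to temperature in B-CPAP stays open, untested.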
